A study of Mus musculus with 34 samples.

How the data were processed

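Poly(A) RNA-seq of whole embryonic mouse lungs was available for 34 libraries in 10 groups. Control lungs and lungs with global Lin28A overexpression were collected at embryonic day 12.5 (n = 3 and n = 3), day 14.5 (n = 3 and n = 4), day 16.5 (n = 3 and n = 3) and day 18.5 (n = 5 and n = 5). At day 18.5 there were also lungs with Lin28A in epithelial cells (n = 3) and in mesenchymal cells (n = 2). Lin28A is an RNA-binding protein that blocks maturation of the let-7 microRNAs, and let-7 lowers many growth-related transcripts. The libraries with global expression carry the tag Vasa in their titles, the epithelial ones Nkx2.1 and the mesenchymal ones Wt1, and the labels do not describe the alleles. Per the labels' protocols, doxycycline was given in the drinking water at 1 g/L from embryonic day 0.5. Each deposited column stood for 1 sample and no pooling was stated. The replicates are not stated to be separate animals, litters or library dates, so every p-value measures spread between samples.

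The deposited tables hold, per the labels, 1 raw count per Ensembl gene and library, and the same values as a normalized signal. The signal values deposited by the authors equalled the counts divided by 1 size factor per library, which was checked on the values, and only the counts were used here. Per the submitters' processing notes the tools were bcl2fastq 2.17.1.14, cutadapt (no version), STAR 2.4.2a, HTSeq 0.6.1p1 and DESeq2 1.10.1 with the genome build GRCm38. The role of each tool, the annotation release and the strandedness of the counting are not stated. Without strand, reads of a gene and of an overlapping or antisense partner cannot be told apart, and counts of near-identical genes (globins, ribosomal protein genes and their copies such as Rps3a3, the Lyz1 and Lyz2 pair, Hox antisense transcripts) are uncertain to that extent. The deposited column of the last day 18.5 mesenchymal library is headed Wt2 where the sample title reads Wt1. It was matched by day and replicate number, being the only column left for that sample.

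The tables hold 21789 genes, each with at least 6 counts in 1 library, so genes below that were removed before deposit and the sums are of the deposited genes. Gene symbols and coordinates came from GENCODE M21 (GRCm38), in which 21754 of the identifiers were found and 35 were not. Total counts per library ranged from 7147301 to 17624884. Intervals of count ratios are exact 95% binomial intervals over a group's summed counts, and a fold against a group with no counts was computed against 3 counts over the group. Such intervals and floors cover counting error only, since PCR copies are not independent molecules.

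Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The genes kept by filterByExpr on the groups (18319) were scaled by TMM and fitted with 1 quasi-likelihood model of 34 libraries and 10 group means (24 residual degrees of freedom, common biological coefficient of variation 0.172). A total of 14 comparisons were tested: 6 of transgenic with control lungs, 3 steps between control stages, 3 tests of whether the global effect differed between successive stages, and direct comparisons of epithelial with mesenchymal and of global with epithelial lungs. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Unless another test is named, each adjusted p of a gene is from edgeR's quasi-likelihood test, each fold is a log2 fold with its standard error, and each level is the mean of counts scaled to the normalized library total (CPM) with the SD between libraries. The log2 CPM values used for scores and plots have a prior count of 2.

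There were 35 gene lists: let-7 targets; alveolar type 2, alveolar type 1, distal tip progenitor, multiciliated, club, basal and neuroendocrine cells; smooth muscle, lipofibroblasts, elastic fibre and collagen matrix, mesothelium and pericytes; endothelium, aerocytes and lymphatics; leukocytes and erythroid cells; cardiomyocytes, thymus, skeletal muscle, nerve and hepatocytes as tissues other than lung; mitosis and S phase, ribosomal proteins, oxidative phosphorylation, glycolysis, sterol and fatty acid synthesis, the insulin-like growth factor pathway, imprinted growth genes, Hox genes, Wnt targets, glucocorticoid-responsive genes, immediate early genes and p53 targets. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated per list, which is the stricter test. A list's adjusted p is from the preset correlation unless the text says otherwise. Counts of list members that rose or fell use the adjustment over all genes, followed by counts adjusted over the list alone.

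Genes were named by a rule. Lin28a, Lin28b, Ddx4 (Vasa), Nkx2-1 and Wt1 were always named. In each of the 6 transgenic comparisons the 10 called genes with the largest rise and the 10 with the largest fall were named, among genes of at least 5 CPM in the higher group and with no overlap between the groups' libraries, leaving out Xist, Tsix, Y-linked genes, globins and unnamed models. Up to 4 called members with the smallest p came from each list past the list test, and members not called could be added where their count was discussed. The other comparisons had 5 genes per direction. A gene named by 2 parts of the rule counts under both. Genes picked by the rule but not reported here were not replaced. The lists, comparisons, tests, naming rule and first set of alternatives were fixed before the data were examined.

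A maturation score per library was the mean log2 CPM of the 200 genes that rose most clearly between control stages less that of the 200 that fell, from a pair of stages holding none of the libraries compared. It was compared by exact permutation tests, two-sided by doubling the smaller tail. Log2 folds of the day 18.5 comparisons were correlated across genes and set against 20 simulations in which unchanged groups shared the same controls. Matches to the let-7 seed were counted in annotated 3′ untranslated regions with Biostrings 2.70.1. All tests across genes were first tested on simulated data: of the genes simulated at a 4-fold change, 81% were recovered in the day 12.5 design, 86% at day 14.5, 77% at day 16.5, 84% in the global, 90% in the epithelial and 90% in the mesenchymal design at day 18.5, each over 18319 genes.

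Alternatives were RLE size factors, no filter, DESeq2 1.42.0, a fit of the compared groups alone, 1 surrogate variable (sva 3.50.0), a block per replicate number, fry in place of camera, other sizes and stages of the score, and leaving out each library. After the data were seen, 5 libraries were also left out together: day 14.5 control 3, which carried thymus transcripts, and replicates 1 and 2 of the day 18.5 control and global groups, which were shallower. Also added were an embryo sex term, a depth term, fits with replicates 1 and 2 or 3 to 5 of day 18.5 alone, and, for the stage and direct comparisons, list tests and fits without those 5 libraries or 1 library. No sample was removed from the values given first. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.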

Results

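Transcript counts were measured in 34 whole mouse lungs collected between E12.5 and E18.5, the period in which the branching lung forms its airways and then its alveolar cells. Lin28A was overexpressed throughout the embryo, in lung epithelium or in lung mesenchyme, and the question was how its presence changed lung development. Control and global groups held 3 and 3 libraries at E12.5, 3 and 4 at E14.5, 3 and 3 at E16.5 and 5 and 5 at E18.5. The epithelial group held 3 libraries and the mesenchymal group 2. Total counts per library ranged from 12901689 to 17624884 at E12.5, 9928631 to 15500555 at E14.5, 11084917 to 12712848 at E16.5 and 7147301 to 13590762 at E18.5. Values after ± are standard errors for log2 folds and SDs between libraries for levels.

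Lin28a (ENSMUSG00000050966, chromosome 4, 134003330 to 134018841) was between 0.192 and 4.15 CPM in every control library and between 289 and 1301 CPM in every transgenic one. The counts do not separate the transgene from the endogenous gene. The mean level was 328 ± 39.6 CPM in global lungs at E12.5 (n = 3), 351 ± 46.5 at E14.5 (n = 4), 360 ± 56.5 at E16.5 (n = 3) and 531 ± 123 at E18.5 (n = 5). It was 952 ± 339 CPM in epithelial lungs (n = 3) and 481 ± 97.9 in mesenchymal lungs (n = 2), against 1.25 ± 1.07 in E18.5 controls (n = 5). Lin28b, the second Lin28 gene (chromosome 10, 45376620 to 45486395), was higher in global lungs at E16.5 (log2 fold 2.08 ± 0.48, edgeR adjusted p = 0.00109) and E18.5 (2.05 ± 0.44, adjusted p = 0.000163). It was also higher in mesenchymal lungs (1.504 ± 0.56, adjusted p = 0.0233), a call that ended without mesenchymal library 1 (log2 fold 1.61), mesenchymal library 2 (1.39) or control 3 (1.32). It was not called in epithelial lungs (-1.07 ± 0.72, adjusted p = 0.266) or at E12.5 (0.82 ± 0.38, adjusted p = 0.507) and E14.5 (0.91 ± 0.39, adjusted p = 0.125). Ddx4, the germ cell gene Vasa, stayed under 1 CPM on average in all 10 groups and was not called in any comparison with controls.

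**Figure D1:**
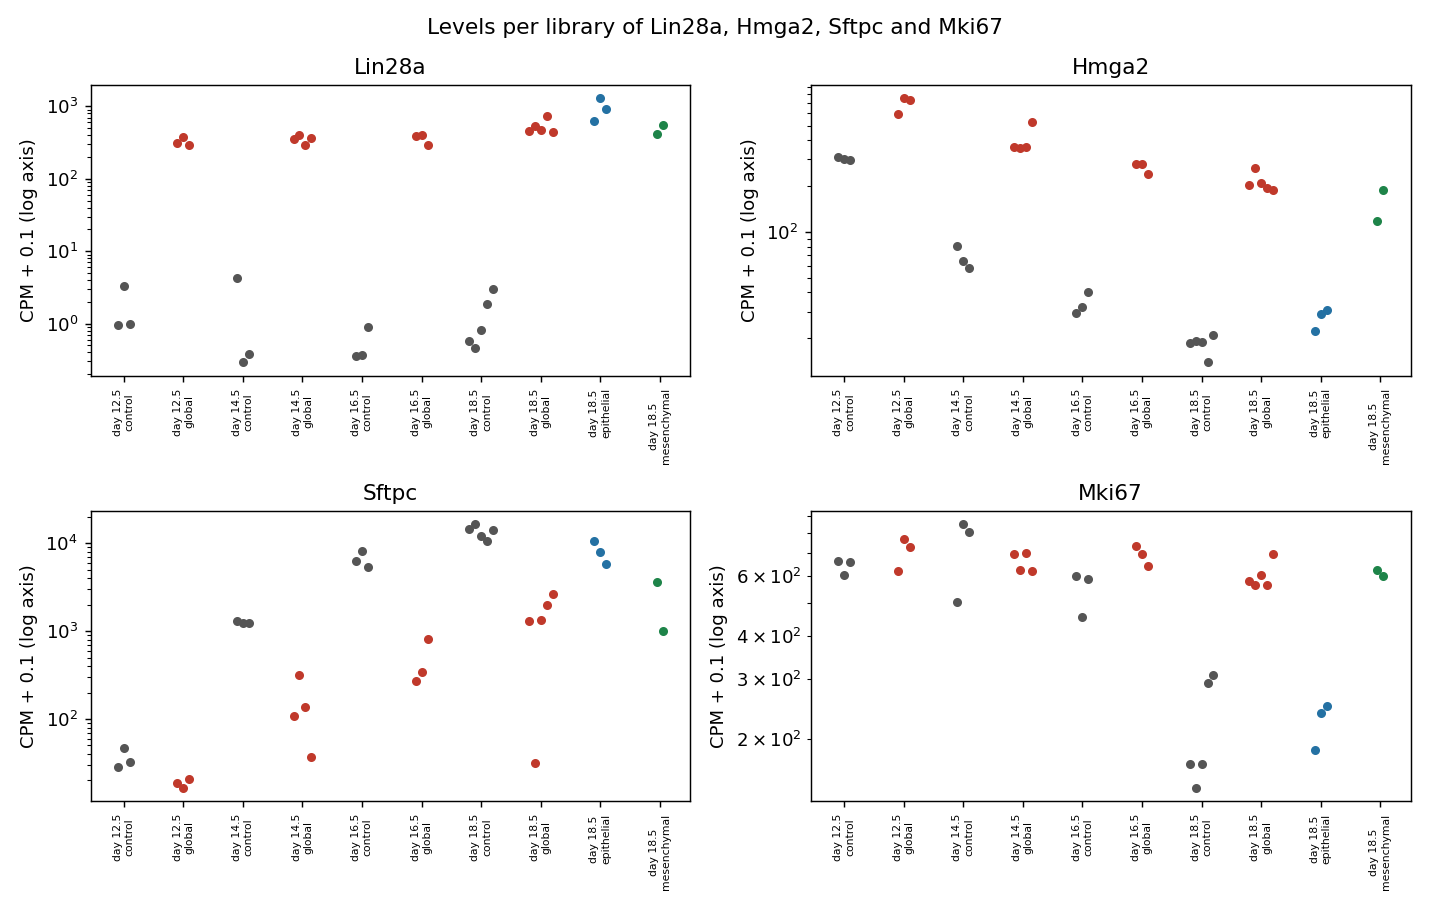
CPM plus 0.1 (log axis) of Lin28a, of the let-7 target Hmga2, of the surfactant gene Sftpc and of the proliferation gene Mki67 in each library, 1 point per library, by group. Hmga2 fell from 303 to 18.3 CPM between E12.5 and E18.5 in control means and was 212 CPM in E18.5 global lungs, where mean Sftpc was 1456 CPM against 13630 in controls.

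At E12.5 the question was which transcripts respond first to global Lin28A. Targets of let-7 rose: Hmga2 (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), a chromatin protein of growing embryonic cells, went from 303 ± 7.14 to 694 ± 86.6 CPM (n = 3 and n = 3; log2 fold 1.20 ± 0.17, edgeR adjusted p = 0.00047). Igf2bp1, which stabilizes growth-related mRNAs, went from 133 ± 22.8 to 254 ± 9.74 CPM (0.93 ± 0.17, adjusted p = 0.0114). The ARID-domain DNA-binding genes Arid3b (0.95 ± 0.17, adjusted p = 0.00665) and Arid3a (0.67 ± 0.12, adjusted p = 0.0114) rose with them. Of 40 let-7 target genes 7 rose, or 20 rose and 1 fell adjusted over the list alone, with a median log2 fold of 0.33 (camera adjusted p = 1.29e-20, or 0.000118 with an estimated correlation). In all, 41 genes were called, 22 higher and 19 lower.

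Other genes that rose at E12.5 were Igdcc3, an immunoglobulin-family membrane protein (log2 fold 1.82 ± 0.22, adjusted p = 2.17e-05), Fignl2, a microtubule-severing ATPase relative (1.61 ± 0.19, adjusted p = 2.17e-05), and Sall4, a stem cell zinc-finger gene (2.03 ± 0.45, adjusted p = 0.0436). Amph (1.15 ± 0.23), of membrane trafficking, and the serine protease Tmprss2 (0.76 ± 0.15) rose at adjusted p = 0.0267. Falls were seen in Adh1, which oxidizes retinol (-1.25 ± 0.20, 118 ± 13.99 to 49.7 ± 7.19 CPM, adjusted p = 0.00214), in the zinc-finger gene Zfp961 (-1.27 ± 0.16, adjusted p = 7.49e-05) and in the lymphatic growth factor Vegfd (-1.19 ± 0.26, adjusted p = 0.0436). The pericyte channel subunit Abcc9 (-1.61 ± 0.35), the endothelial tetraspanin relative Tm4sf1 (-1.34 ± 0.27), the lipoprotein receptor Vldlr (-0.96 ± 0.20), the peptidase Enpep (-0.89 ± 0.16), the fibroblast phospholipase Enpp2 (-0.88 ± 0.17), the immune ligand Clec2d (-1.09 ± 0.24) and the oxidoreductase Pyroxd2 (-0.80 ± 0.16) fell at adjusted p from 0.0114 to 0.0436. Nkx2-1, the transcription factor of lung epithelium (chromosome 12, 56531958 to 56536908), did not pass (-0.07, adjusted p = 0.942), nor did Wt1, of the mesothelium (chromosome 2, 105126529 to 105173616; -0.01, adjusted p = 1).

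Sterol and fatty acid synthesis genes had a median of 0.31 over 27 genes (adjusted p = 2.18e-11, or 0.0839 with an estimated correlation), with 5 risers adjusted over the list alone and 13 at an unadjusted p under 0.05. Oxidative phosphorylation genes had a median of -0.20 over 75 genes (adjusted p = 4.14e-15, or 0.363 likewise), with 20 lower at an unadjusted p under 0.05. Leukocyte genes had a median of -0.36 over 19 genes (adjusted p = 1.33e-06, or 0.252 likewise). Cardiomyocyte genes had the lowest median, -1.43 over 18 genes (adjusted p = 1.18e-13, or 0.252 likewise), and skeletal muscle genes had -1.27 over 10 genes (adjusted p = 0.000149, or 0.363 likewise). Neither muscle list had a called member by edgeR; 6 cardiomyocyte and 2 skeletal muscle genes were lower at an unadjusted p under 0.05, and DESeq2 called 1 cardiomyocyte gene. Mean log2 CPM of the cardiomyocyte list was 3.32, 5.94 and 5.67 in the 3 control libraries and 4.98, 0.53 and 0.83 in the 3 global ones. Whether other E12.5 falls followed these levels was not tested.

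Smaller shifts at E12.5 passed the list test at the preset correlation but not with an estimated correlation, where adjusted p ran from 0.123 to 0.613. Their medians were -0.31 for alveolar type 1 genes (adjusted p = 0.000184), -0.39 for alveolar type 2 genes (0.0334), -0.48 for club cell genes (0.0454), -0.16 for lipofibroblast genes (0.011), -0.20 for matrix genes (7.44e-05), -0.08 for pericyte genes (0.0284), -0.21 for endothelial genes (0.00394), -0.41 for aerocyte genes (0.012), -0.30 for nerve genes (0.0227), -0.14 for ribosomal protein genes (0.000113) and 0.25 for Hox genes (0.00589). With genes that had no counts in a group set at their bound, the medians were -0.34 for alveolar type 2, -0.20 for club, -0.14 for lipofibroblast and -0.02 for pericyte genes. The other 18 lists did not pass, with adjusted p from 0.0995 (smooth muscle and lymphatic genes) to 0.973 (distal tip genes). The number of called genes rested on single libraries, being 8 without control 3 and 361 without global 1, the only global library high in cardiomyocyte genes. Lin28a, Hmga2, Igdcc3, Fignl2, Arid3b, Zfp961 and Adh1 stayed called when any 1 library was left out. The other 13 named genes kept their direction but lost their calls without control 3, as they did without global 3, Sall4 then standing at 1.85 and 2.16, Igf2bp1 at 0.80 and 0.94 and Vegfd at -1.30 and -1.25. Without control 2 or global 2, 11 lost them each.

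**Figure D2:**
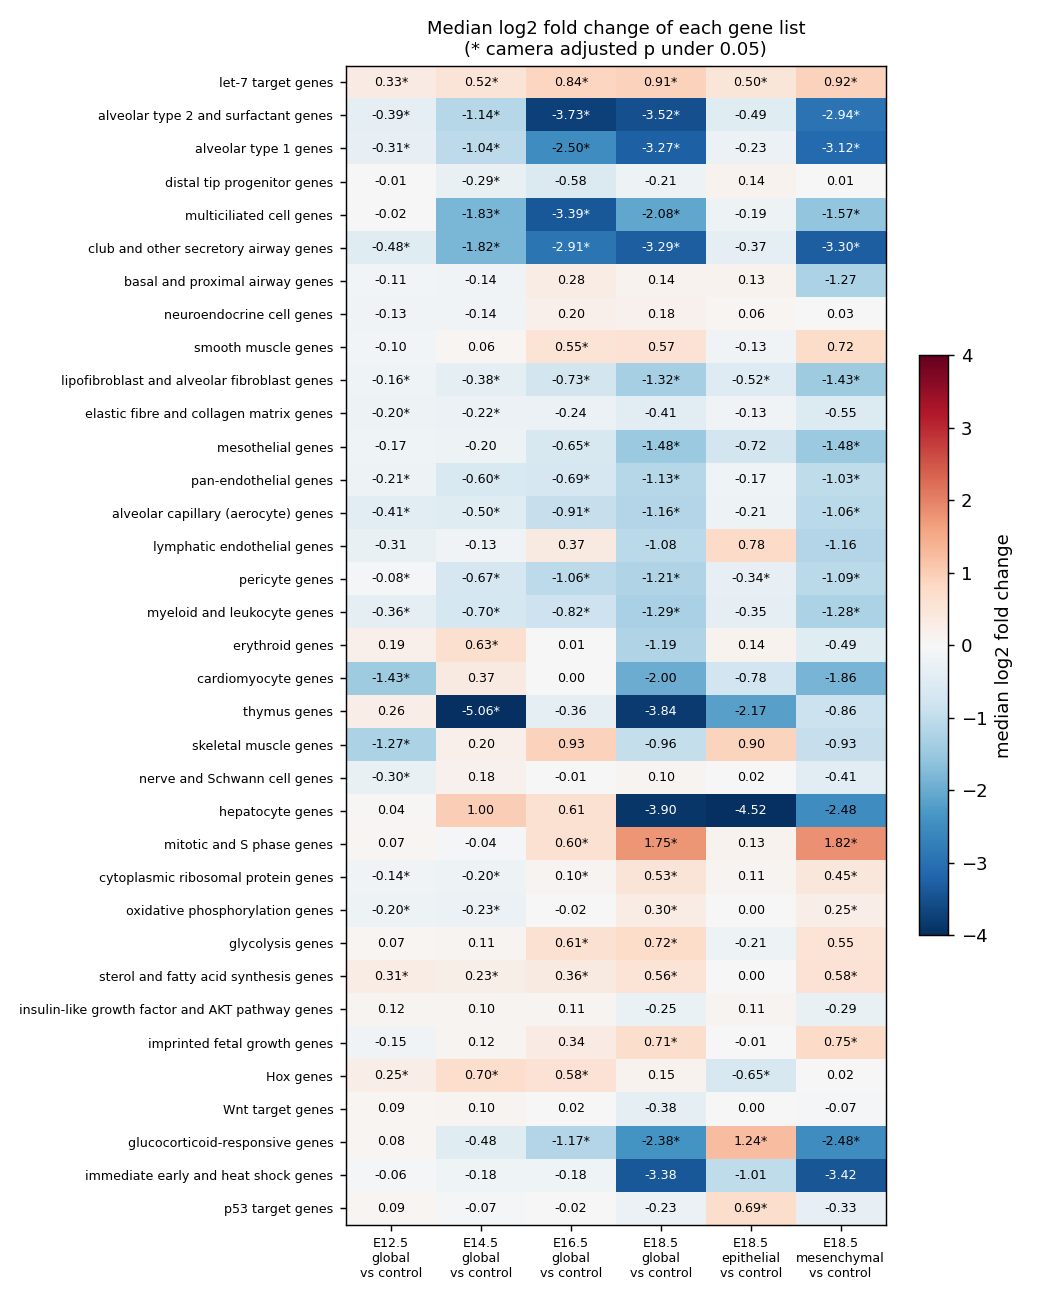
Median log2 fold of the members of each of the 35 lists (rows) in the 6 comparisons with controls (columns), colour and printed value on the same log2 scale, an asterisk marking a camera adjusted p under 0.05 at the preset correlation. Let-7 targets are above 0 in all 6 columns, from 0.33 to 0.92, while alveolar type 2 genes reach -3.73 at E16.5.

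At E14.5 the comparison asked how the start of epithelial differentiation was affected. Surfactant gene Sftpc (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081) was 149 ± 118 CPM in global lungs (n = 4) against 1255 ± 38.6 in controls (n = 3; log2 fold -3.07 ± 0.68, edgeR adjusted p = 0.00287). Sftpb was 11.98 ± 3.43 against 61.7 ± 1.23 CPM (-2.36 ± 0.43, adjusted p = 0.000514). The alveolar type 1 receptor gene Ager was 17.8 ± 2.63 against 84.8 ± 4.38 CPM (-2.26 ± 0.31, adjusted p = 2.11e-05), and Foxj1, the switch gene of motile cilia, was 1.97 ± 0.939 against 14.3 ± 2.24 CPM (-2.84 ± 0.47, adjusted p = 0.000157). Hmga2 rose from 67.6 ± 11.7 to 401 ± 85.4 CPM (2.57 ± 0.18, adjusted p = 7.82e-11). In all, 2361 genes were called, 814 higher and 1547 lower.

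Of 20 alveolar type 2 genes 9 fell and 1 rose, or 12 and 1 adjusted over the list alone (median -1.139, camera adjusted p = 5.32e-08, or 0.235 with an estimated correlation). They included the mucin gene Muc1 (-2.36 ± 0.27), the protease gene Ctsh (-2.17 ± 0.34), which trims surfactant proteins, and Dram1 (-1.98 ± 0.31). Of 19 alveolar type 1 genes 14 fell, adjusted over the list alone too (median -1.04, adjusted p = 1.89e-14, or 0.0402 likewise). They included the tight junction gene Cldn18 (-1.45 ± 0.20), the sodium channel gene Scnn1g (-1.79 ± 0.27) and Emp2 (-1.24 ± 0.21). Of 36 multiciliated genes 20 fell, or 25 with 1 riser adjusted over the list alone (median -1.83, adjusted p = 2.56e-13, or 0.206 likewise). They included the ciliogenesis regulators Mcidas (-2.55 ± 0.49) and Ccno (-1.65 ± 0.30) and the cilia gene Lrrc23 (-3.46 ± 0.76). Of 14 club cell genes 7 fell (median -1.82, adjusted p = 8.54e-06, or 0.113 likewise). They included the detoxifying enzyme Cyp2f2 (-3.19 ± 0.57), the secretory genes Scgb3a2 (-2.37 ± 0.46) and Lypd2 (-1.88 ± 0.43), and Gabrp, with 1 count over the global libraries and 29 over the controls (31.7-fold lower, 95% interval 5.25 to 1293; not called without control 3). Of 17 distal tip genes 5 fell and 1 rose (adjusted p = 0.0186, or 0.46 likewise). Clu (-1.85 ± 0.22), Id2 (-0.68 ± 0.15) and Bmp4 (-0.50 ± 0.15, and not called without control 2, control 3, global 1 or global 4) fell while the growth gene Mycn rose (0.70 ± 0.19, and 0.58 and not called without control 3). Among the genes that fell most were also Sec14l3, a lipid-binding gene of airway cells (-3.82 ± 0.90), the amino acid transporter Slc6a14 (-3.36 ± 0.45) and the chloride channel Clic3 (-3.23 ± 0.42). Nkx2-1 was lower (-0.47 ± 0.15, adjusted p = 0.0303), a call that ended without control 1 (-0.28), control 2 (-0.48), global 3 (-0.45) or global 4 (-0.40).

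In the mesenchyme and vessels, 6 of 16 lipofibroblast genes fell (adjusted p = 0.00104, or 0.181 with an estimated correlation). They included the matrix ligand Npnt (-0.82 ± 0.12) and the mesenchymal transcription factor Tcf21 (-0.48 ± 0.11). Of 18 matrix genes 4 fell (adjusted p = 0.00115, or 0.403 likewise). They included the crosslinking enzyme Lox (-0.99 ± 0.14), Mfap4 (-0.99 ± 0.16) and Tnc (-1.26 ± 0.22). Of 16 endothelial genes 14 fell, or 16 adjusted over the list alone (median -0.60, adjusted p = 1.82e-11, or 0.0848 likewise). The adhesion gene Pecam1 was at 158 ± 22.1 against 264 ± 8.10 CPM (-0.74 ± 0.12, adjusted p = 8.84e-05). Of 8 aerocyte genes 4 fell (adjusted p = 0.00664, or 0.0782 likewise). They included Apln (-0.85 ± 0.16). Of 13 pericyte genes 6 fell (adjusted p = 6.91e-06, or 0.0782 likewise). They included the potassium channel genes Kcnj8 (-1.18 ± 0.21) and Abcc9 (-1.52 ± 0.30), Cox4i2 (-1.57 ± 0.22) and Higd1b (-3.20 ± 0.47). Of 23 Hox genes 6 rose (median 0.70, adjusted p = 7.25e-07, or 0.113 with an estimated correlation), led by Hoxb4 (0.69 ± 0.12), Hoxb6 (0.85 ± 0.19) and Hoxb8 (1.06 ± 0.27, and 0.82 and not called without control 3). Hoxd13 had 25 counts in global and 2 in control libraries (11.5-fold, 95% interval 2.86 to 99.7; not called without control 2, control 3 or global 4, and a log2 fold of 5.78 against 3.27 without control 1). Sterol synthesis genes gave 4 risers and 1 faller of 27 (adjusted p = 0.00104, or 0.359 likewise), with the fatty acid elongase Elovl6 up (0.60 ± 0.14). Oxidative phosphorylation genes gave 12 fallers of 75 (adjusted p = 8.54e-07, or 0.641 likewise).

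Let-7 targets again rose, 20 of 40 with 1 falling, or 25 and 1 adjusted over the list alone (median 0.52, adjusted p = 1.59e-23, or 4.78e-05 with an estimated correlation). They included the mRNA-binding genes Igf2bp2 (1.27 ± 0.14, 138 ± 17.7 to 333 ± 32.6 CPM) and Igf2bp3 (0.82 ± 0.11) and Arid3a (1.07 ± 0.12). Also higher were Sall4 (4.53 ± 0.58), the ephrin receptor Epha8 (3.11 ± 0.40), the retinol transporter Stra6 (3.09 ± 0.37, 1.999 ± 0.554 to 17.0 ± 4.68 CPM) and the cannabinoid receptor Cnr1 (2.57 ± 0.30). The kidney-type genes Miox (6.33 ± 1.39), Kap (6.30 ± 1.62) and Fxyd2 (4.02 ± 0.95) were high in global library 4, Kap being at 264 CPM there and from 2.90 to 6.42 CPM in the other global libraries. Without that library their log2 folds were 3.67, 2.27 and 1.49, and Kap and Fxyd2 were not called, nor was Kap without control 2 or control 3. Without control 1 Kap was at a log2 fold of 12.76 and Miox of 10.003. Erythroid genes (5 of 17 higher, adjusted p = 0.0436, or 0.697 with an estimated correlation) rested partly on the same library, the embryonic globin Hbb-bh1 going from 2.28 to 0.79 without it (not called either without control 2 or control 3). Rps3a3, a ribosomal protein gene copy (5.75 ± 1.18), rested on global library 1 (2.96 without it).

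Leukocyte and thymus genes fell together at E14.5, and the thymus part came from control library 3. Of 19 leukocyte genes 12 fell, or 15 adjusted over the list alone (median -0.70, adjusted p = 1.03e-07, or 0.113 with an estimated correlation). Of 9 thymus genes 6 fell, or 8 adjusted over the list alone (median -5.06, or -2.63 with unseen genes at their bound, adjusted p = 0.039, or 0.697 with an estimated correlation). Without control 3 the counts were 3 of 19 leukocyte genes and no called thymus gene (adjusted p = 0.386, 8 of 9 genes having been lower at an unadjusted p under 0.05 with it). The recombination gene Rag1 went from -8.11 to 0.24, Themis from -5.21 to 0.55 and the kinase Lck from -1.67 to 0.43. The thymus protease Prss16 went from -6.13 to -1.66, the T cell genes Cd3g from -7.60 to -0.65 and Thy1 from -2.94 to -0.55, Fam169b from -3.06 to -0.85, and the leukocyte genes Ptprc from -2.18 to -0.65 and Coro1a from -1.13 to -0.35, none called. The leukocyte adhesion ligand gene Selplg stayed called (-2.98 with and -1.79 without it), and the macrophage lysozyme Lyz2 fell by 1.89 ± 0.31 on the log2 scale. Without control 3, 18 let-7 targets rose and 1 fell, 9 alveolar type 2, 13 alveolar type 1, 13 multiciliated, 5 club and 13 endothelial genes fell, 2 Hox genes rose (7 adjusted over the list alone) and 1263 genes were called in all.

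**Figure D3:**
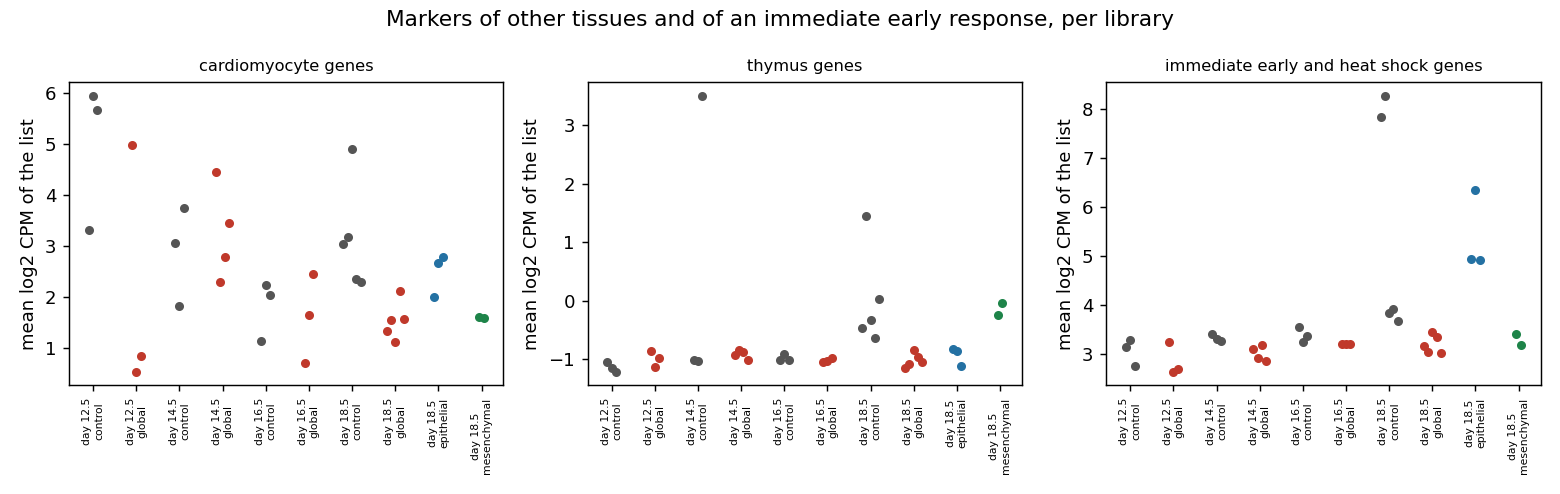
Mean log2 CPM of the cardiomyocyte, thymus and immediate early lists in each library, 1 point per library, by group. E12.5 global libraries span 0.53 to 4.98 for cardiomyocyte genes, 1 E14.5 control lies far above all other libraries for thymus genes, and E18.5 controls 1 and 2 reach 7.83 and 8.25 for immediate early genes against 3.68 to 3.91 in controls 3 to 5.

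At E16.5, when controls had begun alveolar differentiation, the comparison asked how far global lungs had followed. The phosphate transporter Slc34a2 of alveolar type 2 cells was 8.88 ± 6.64 CPM in global lungs against 639 ± 166 in controls (n = 3 and n = 3; log2 fold -6.17 ± 0.87, edgeR adjusted p = 2.27e-06). The surfactant lipid transporter Abca3 (chromosome 17, 24351950 to 24410201) was 62.8 ± 15.8 against 462 ± 51.7 CPM (-2.88 ± 0.28, adjusted p = 7.18e-09). Among alveolar type 1 genes, Ager (chromosome 17, 34597862 to 34600936) was 29.6 ± 8.12 against 645 ± 151 CPM (-4.45 ± 0.37, adjusted p = 7.53e-10) and the homeodomain gene Hopx was 10.7 ± 2.78 against 228 ± 57.5 CPM (-4.42 ± 0.38, adjusted p = 1.29e-09). The airway secretoglobin Scgb1a1 was 0.320 ± 0.209 against 31.2 ± 11.4 CPM (-6.56 ± 0.94, adjusted p = 5.8e-06). In all, 6785 genes were called, 3106 higher and 3679 lower.

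Of 20 alveolar type 2 genes 19 fell, or 20 adjusted over the list alone (median -3.73, camera adjusted p = 4.02e-17, or 0.0668 with an estimated correlation). Sftpd was at -6.37 ± 0.99, Ctsh at -3.70 ± 0.39, Muc1 at -3.01 ± 0.30 and the differentiation factor Cebpa at -2.58 ± 0.28. Of 19 alveolar type 1 genes 17 fell and 2 rose, adjusted over the list alone too (median -2.50, adjusted p = 1.31e-19, or 0.00797 likewise). They included the water channel Aqp5 (-5.85 ± 0.73), Emp2 (-2.76 ± 0.23) and Gprc5a (-2.81 ± 0.25). Of 36 multiciliated genes 35 fell (median -3.39, adjusted p = 2.33e-19, or 0.115 likewise). They included Fam183b (-5.14 ± 0.66), Stk33 (-4.31 ± 0.53), Hydin (-2.94 ± 0.38), Ccdc40 (-2.29 ± 0.26) and Ccdc153, with 3 counts against 226 (80.7-fold lower, 95% interval 27.3 to 394; fitted log2 fold -9.36 without global 3 and -6.17 with it). Of 14 club cell genes 9 fell and 1 rose (median -2.91, adjusted p = 0.000323, or 0.218 likewise). They included Cbr2 (-4.10 ± 0.56), Hp (-3.58 ± 0.43) and Upk3a (-3.41 ± 0.47). Also among the strongest fallers were Mlc1 (-6.52 ± 0.87), Mslnl (-5.93 ± 0.66), the lysozyme gene Lyz1 (-5.92 ± 1.11), the chitinase Chia1 (-5.65 ± 1.25, and -3.44 without control 2) and the secreted factor Retnla, with 3 counts against 530 (189-fold lower, 95% interval 64.4 to 920). Glucocorticoid-responsive genes, 6 of 9 lower or 7 adjusted over the list alone (median -1.17, adjusted p = 2.1e-05, or 0.173 with an estimated correlation), included the sodium channel gene Scnn1a (-3.96 ± 0.35), the cortisone-activating enzyme Hsd11b1 (-3.61 ± 0.42), Zbtb16 (-2.64 ± 0.45) and the clock gene Per1 (-1.55 ± 0.23). Nkx2-1 was 433 ± 18.7 against 714 ± 52.1 CPM (-0.72 ± 0.16).

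Outside the epithelium, 13 of 16 lipofibroblast genes fell (median -0.73, adjusted p = 1.55e-10, or 0.00797 with an estimated correlation). They included Npnt (-1.78 ± 0.13, 609 ± 52.5 to 177 ± 7.72 CPM), the lipase Ces1d (-2.19 ± 0.18), Tcf21 (-1.37 ± 0.11) and Limch1 (-1.20 ± 0.15). All 16 endothelial genes fell (median -0.69, adjusted p = 3.4e-07, or 0.19 with an estimated correlation), Pecam1 by 0.91 ± 0.13 and the receptor Kdr by 0.61 ± 0.10 on the log2 scale. Of 8 alveolar capillary (aerocyte) list genes 6 fell in whole-lung RNA (adjusted p = 0.00386, or 0.0419 likewise). They included the capillary lipase anchor Gpihbp1 (-2.23 ± 0.30) and Ednrb (-1.05 ± 0.16). Of 13 pericyte genes 11 fell (median -1.06, adjusted p = 2.36e-05, or 0.0739 likewise). They included Lamc3 (-2.29 ± 0.28). Of 19 leukocyte genes 16 fell (adjusted p = 4.27e-05, or 0.24 likewise). They included Mpeg1 (-1.38 ± 0.27). Of 12 mesothelial genes 4 fell (adjusted p = 0.0327, or 0.494 likewise). Msln was at -3.93 ± 0.46. Smooth muscle genes went the other way, 6 of 13 higher and 1 lower (median 0.55, adjusted p = 0.00921, or 0.494 with an estimated correlation), with the contractile genes Cnn1 (1.79 ± 0.22) and Actg2 (1.41 ± 0.20) and their activator Myocd (1.61 ± 0.30).

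Of 40 let-7 targets 26 rose and 2 fell, adjusted over the list alone too (median 0.84, adjusted p = 2.03e-16, or 0.00076 with an estimated correlation). Hmga2 went from 33.7 ± 5.52 to 267 ± 22.6 CPM (2.98 ± 0.19, adjusted p = 1.23e-11), Igf2bp1 from 57.5 ± 2.24 to 203 ± 10.3 CPM (1.82 ± 0.18), Igf2bp2 rose by 1.67 ± 0.15 and the ubiquitin-conjugating enzyme Cdc34 by 1.45 ± 0.11. Mitotic genes rose, 24 of 37 or 28 adjusted over the list alone (median 0.60, adjusted p = 3.4e-07, or 0.494 with an estimated correlation). They included the replication genes Mcm7 (0.80 ± 0.16) and Cdc6 (1.09 ± 0.22). Glycolysis genes (11 risers and 1 faller of 16), sterol genes (13 and 3 of 27), ribosomal protein genes (14 and 1 of 83) and Hox genes (6 and 0 of 23) shifted upward at adjusted p from 0.000648 to 0.0254, and from 0.322 to 0.817 with an estimated correlation. The largest rises included the neuronal adhesion gene Cntn2, with no counts in controls and 5.50 ± 0.951 CPM in global lungs (at least 63.8-fold higher), and Sall4, with 281 counts against 3 (87.5-fold, 95% interval 29.6 to 427). The cartilage collagen Col2a1 (4.93 ± 1.04, 4.88 ± 1.40 to 149 ± 24.6 CPM), Epha8 (4.90 ± 0.50), the retinoic acid carrier Crabp2 (4.47 ± 0.41), the amino acid transaminase Bcat1 (4.17 ± 0.55), the potassium channel Kcnk16 (4.12 ± 0.43), the septin Sept3 (3.79 ± 0.27) and the neural catenin Ctnna2 (3.75 ± 0.40) rose as well.

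At E18.5, just before birth, 11872 of 18319 genes were called in global lungs, 5876 higher and 5996 lower, and 2004 rose and 3059 fell at least 2-fold. Aqp5 (chromosome 15, 99590782 to 99594829) was 0.306 ± 0.131 CPM in global lungs and 168 ± 88.3 in controls (n = 5 and n = 5; log2 fold -9.08 ± 0.47, edgeR adjusted p = 5.2e-15). Abca3 was 113 ± 34.5 against 704 ± 65.1 CPM (-2.63 ± 0.21, adjusted p = 1.03e-11), and Scgb1a1 (chromosome 19, 9083636 to 9087958) was 6.60 ± 3.91 against 735 ± 401 CPM (-6.76 ± 0.52, adjusted p = 2.83e-11). The replication gene Mcm7 was 220 ± 20.02 against 55.1 ± 16.4 CPM (1.99 ± 0.13, adjusted p = 1.84e-13) and Hmga2 was 212 ± 29.0 against 18.3 ± 2.65 CPM (3.54 ± 0.15, adjusted p = 4.09e-16).

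All 20 alveolar type 2 genes fell, adjusted over the list alone too (median -3.52, camera adjusted p = 3.39e-10, or 0.136 with an estimated correlation). They included Chil1 (-6.49 ± 0.45), the complement gene Hc (-6.08 ± 0.43) and Sftpc (-3.23 ± 0.59), which ranged from 31.8 to 2621 CPM between global libraries. Of 19 alveolar type 1 genes 18 fell and 1 rose (median -3.27, adjusted p = 1.97e-17, or 0.0145 likewise). They included the basement membrane collagen Col4a3 (-4.19 ± 0.23), Gprc5a (-3.61 ± 0.20) and Rtkn2 (-2.97 ± 0.16). Of 36 multiciliated genes 30 fell and 1 rose (median -2.08, adjusted p = 2.97e-06, or 0.481 likewise). They included Ccdc153 (-3.21 ± 0.37) and Tppp3 (-1.68 ± 0.16). Of 14 club cell genes 11 fell and 1 rose (median -3.29, adjusted p = 0.00182, or 0.258 likewise). They included Cbr2 (-4.14 ± 0.41), Hp (-3.47 ± 0.31) and Chad (-3.10 ± 0.23). All 9 glucocorticoid-responsive genes fell (median -2.39, adjusted p = 3.9e-06, or 0.136 likewise). They included Scnn1a (-4.66 ± 0.27), Zbtb16 (-3.64 ± 0.33), Klf9 (-2.39 ± 0.18) and Tsc22d3 (-1.72 ± 0.12). Other strong fallers were the esterase Pon1 (-7.88 ± 0.51), the ligand Wnt3a (-7.73 ± 0.52), complement C6 (-7.43 ± 0.53), the protease inhibitor Spink5 (-7.42 ± 0.73), Lyz1 (-7.26 ± 0.56), the cytochrome Cyp2e1 (-6.85 ± 0.74) and Gdpd2 (-6.58 ± 0.57). Nkx2-1 fell by 0.34 ± 0.12 on the log2 scale (adjusted p = 0.0145), a call that ended without control 4 (-0.23) or global 5 (-0.28).

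In the stroma and vessels all 16 lipofibroblast genes fell (median -1.32, adjusted p = 5.83e-11, or 0.0145 with an estimated correlation). They included Enpp2 (-2.86 ± 0.14, 189 ± 32.9 to 26.1 ± 5.93 CPM), Ces1d (-2.50 ± 0.14), Npnt (-1.998 ± 0.10) and Tcf21 (-1.43 ± 0.09). All 16 endothelial genes fell (median -1.13, adjusted p = 8.83e-09, or 0.136 likewise). They included Pecam1 (-1.29 ± 0.10), Kdr (-1.28 ± 0.08) and the tight junction gene Cldn5 (-1.90 ± 0.17). Of 8 aerocyte genes 6 fell and 1 rose (adjusted p = 0.0186, or 0.117 likewise). The carbonic anhydrase Car4 was at -5.11 ± 0.49 and Apln at -1.85 ± 0.14. Of 13 pericyte genes 11 fell (median -1.21, adjusted p = 5.43e-06, or 0.0965 likewise). Lamc3 was at -3.30 ± 0.21. Of 12 mesothelial genes 11 fell (median -1.48, adjusted p = 0.000186, or 0.17 likewise). Msln was at -4.19 ± 0.34 and Wt1 itself at 3.97 ± 1.97 against 7.24 ± 1.27 CPM (-0.83 ± 0.23, adjusted p = 0.00241). All 19 leukocyte genes fell (median -1.29, adjusted p = 3.9e-06, or 0.168 likewise). Lyz2 was at -3.54 ± 0.26 and the receptor Csf1r at -1.14 ± 0.09.

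All 37 mitotic genes rose (median 1.75, adjusted p = 1.07e-26, or 0.117 with an estimated correlation). They included Cdc6 (2.68 ± 0.19), Chaf1b (2.30 ± 0.16) and Mki67 (1.47 ± 0.16, 216 ± 77.3 to 602 ± 54.4 CPM). Of 40 let-7 targets 30 rose and 6 fell (median 0.91, adjusted p = 2.57e-08, or 0.0145 with an estimated correlation). They included Mycn (2.92 ± 0.18, 12.9 ± 2.84 to 98.8 ± 21.4 CPM), the cyclin Ccnd2 (1.67 ± 0.09) and Cdc34 (1.54 ± 0.09). Ribosomal protein genes (70 risers and 1 faller of 83, median 0.53), oxidative phosphorylation genes (45 and 2 of 75), imprinted growth genes (8 and 3 of 11), glycolysis genes (10 and 3 of 16) and sterol genes (17 and 8 of 27) shifted upward at adjusted p from 4.48e-08 to 0.0338, and from 0.17 to 0.747 with an estimated correlation. H19 was at 7635 ± 1440 against 2050 ± 564 CPM (1.90 ± 0.17), and the surfactant-lipid desaturase Scd1 fell by 4.71 ± 0.34. After Lin28a, the largest rises were in the kinesin Kif12 (7.02 ± 0.31, 0.265 ± 0.172 to 37.7 ± 10.1 CPM) and Sall4, with 359 counts against 3 (106-fold, 95% interval 36.0 to 516). The glycosyltransferase B4galnt4 (5.49 ± 0.29), Crabp2 (5.08 ± 0.34), Sept3 (4.83 ± 0.26), the phosphatase Dusp9 (4.70 ± 0.28), Fbxo41 (4.66 ± 0.40), Kcnk16 (4.65 ± 0.37) and the neuronal adhesion gene Ntm (4.63 ± 0.30) followed.

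Some E18.5 differences rested on controls 1 and 2, which with global libraries 1 and 2 had fewer counts (7147301 to 10370668) than the others of the 2 groups (12641558 or more). Immediate early genes, 9 of 10 lower (median -3.38, adjusted p = 0.079), moved with these controls, the transcription factor Fos being 595 ± 801 CPM in controls and 4.22 ± 0.766 in global lungs (-7.13 ± 0.97), and with replicates 3 to 5 of both groups Fos was at -2.42 and the median at -0.61. Hepatocyte genes (8 of 10 lower, median -3.90, adjusted p = 0.643) and cardiomyocyte genes (15 of 18 lower, median -1.996, adjusted p = 0.117) also lost called members without the doubted libraries, leaving 4 cardiomyocyte fallers and 1 hepatocyte riser. The same fit gave 20 alveolar type 2 fallers (median -3.05), 18 alveolar type 1 fallers with 1 riser, 37 mitotic risers (median 1.54), 27 let-7 risers with 5 fallers, 16 lipofibroblast and 15 endothelial fallers and 9 glucocorticoid fallers (median -1.70).

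With Lin28A in epithelial cells, as the labels give it, the question was which of these changes recurred. Let-7 targets rose in whole-lung RNA. Ccnd2 was 394 ± 57.6 CPM against 125 ± 12.53 (n = 3 and n = 5; log2 fold 1.66 ± 0.10, edgeR adjusted p = 5.92e-13), and Hmga2 rose by 0.57 ± 0.17 (adjusted p = 0.00864). Alveolar genes did not fall as in global lungs, Sftpc being 8134 ± 2405 CPM against 13630 ± 2326 (-0.75 ± 0.64, adjusted p = 0.393). The cell cycle inhibitor Cdkn1a (chromosome 17, 29090976 to 29100727), a p53 target, was 326 ± 93.8 against 61.4 ± 33.2 CPM (2.42 ± 0.26, adjusted p = 2.39e-08). Nkx2-1 did not pass (0.30 ± 0.14, adjusted p = 0.0941). In all, 6077 genes were called, 3291 higher and 2786 lower.

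Of 40 let-7 targets 21 rose, or 23 with 1 faller adjusted over the list alone (median 0.50, camera adjusted p = 9.8e-11, or 0.007 with an estimated correlation). They included the transcription repressors Hic2 (1.94 ± 0.15) and Bach1 (1.11 ± 0.10) and Cdc34 (1.18 ± 0.10). Of 9 p53 targets 8 rose, adjusted over the list alone too (median 0.69, adjusted p = 3.9e-06, or 0.00712 likewise). They included Trp53inp1 (1.81 ± 0.16), the stress gene Sesn2 (0.90 ± 0.14) and the exonuclease Aen (0.69 ± 0.12). Of 9 glucocorticoid-responsive genes 7 rose (median 1.24, adjusted p = 6.04e-05, or 0.352 likewise). They included Sgk1 (2.04 ± 0.30), Klf9 (1.38 ± 0.18), Per1 (1.25 ± 0.20) and Tsc22d3 (1.18 ± 0.13). Of 16 lipofibroblast genes 10 fell, or 11 adjusted over the list alone (median -0.52, adjusted p = 3.38e-05, or 0.138 likewise). They included Tcf21 (-0.86 ± 0.10) and Itga8 (-0.73 ± 0.15). Of 23 Hox genes 10 fell, or 11 adjusted over the list alone (median -0.65, or -0.49 with unseen genes at their bound, adjusted p = 0.00615, or 0.729 with an estimated correlation). They included Hoxb4 (-1.02 ± 0.13) and Hoxa5 (-0.65 ± 0.15, and -0.41 without epithelial library 3). Of 13 pericyte genes 3 fell (adjusted p = 0.0256, or 0.724 likewise). They included Gucy1a1 (-0.65 ± 0.09) and Rgs5 (-0.48 ± 0.15, not called without control 5 at -0.39 or epithelial library 3 at -0.44). Of 30 general epithelial genes, a set chosen after the results were seen, 20 rose and 0 fell (median 0.70), and whether the share of epithelial cells differed was not tested.

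After Lin28a, the largest rises in epithelial lungs were in the mucin-like gene Mucl3 (7.01 ± 0.36, 4.03 ± 1.58 to 545 ± 331 CPM), the nuclear receptor Nr4a3 (6.22 ± 0.47), the receptor partner Ramp3 (5.00 ± 0.49) and Krtap17-1 (4.90 ± 0.56). The protease Prss22 (4.52 ± 0.44), the orexin receptor Hcrtr1 (4.43 ± 0.47), Fam107a (4.20 ± 0.32), Krt87 (4.17 ± 0.44) and the tight junction gene Cldn23 (3.93 ± 0.37) rose as well. The largest falls were in the glutamate receptor gene Grin2c (-3.91 ± 0.93), the protease Ctse (-2.66 ± 0.80, and -2.42 and not called without epithelial library 3), the peptidase relative Ace3 (-2.29 ± 0.41), and Panct2 (-2.23 ± 0.40). Selenbp2 (-2.20 ± 0.38, and -3.67 without epithelial library 2), the macrophage receptor Cx3cr1 (-2.19 ± 0.30), the growth factor Fgf9 (-2.15 ± 0.40, and -3.24 without epithelial library 2), Ism2 (-2.11 ± 0.33), the death receptor Tnfrsf25 (-2.10 ± 0.26) and the endothelial receptor Calcrl (-1.99 ± 0.24, 276 ± 86.1 to 69.3 ± 13.98 CPM) fell too. Alveolar type 2 genes gave 2 fallers of 20 (median -0.49, adjusted p = 0.22), alveolar type 1 genes 5 risers and 6 fallers of 19 (adjusted p = 0.294), multiciliated genes 3 risers and 2 fallers of 36 (adjusted p = 0.638) and mitotic genes 4 risers of 37 (median 0.13, adjusted p = 0.213). Without the doubted controls 1 and 2, immediate early genes turned from a median of -1.01 with 1 riser and 3 fallers of 10 to 8 risers (adjusted p = 7.47e-06, or 0.196 with an estimated correlation) and pericyte genes no longer passed (adjusted p = 0.218). In that fit 22 let-7 targets, 8 p53 targets and 8 glucocorticoid genes rose.

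With Lin28A in mesenchymal cells the changes resembled those of global lungs in direction and size, although only 2 libraries were available. Sftpc was 2323 ± 1847 CPM (n = 2) against 13630 ± 2326 (n = 5; log2 fold -2.55 ± 0.83, edgeR adjusted p = 0.0109) and Aqp5 was 0.488 ± 0.470 against 168 ± 88.3 CPM (-8.38 ± 0.66, adjusted p = 6.01e-11). Hmga2 was 153 ± 49.8 against 18.3 ± 2.65 CPM (3.07 ± 0.17, adjusted p = 1.98e-13), and Mcm7 was 251 ± 45.3 against 55.1 ± 16.4 CPM (2.18 ± 0.16, adjusted p = 1.25e-11). In all, 9952 genes were called, 5016 higher and 4936 lower, and 6588 without mesenchymal library 2. Wt1, whose name tags this line, was 3.13 ± 0.737 against 7.24 ± 1.27 CPM (-1.21 ± 0.32, adjusted p = 0.00238), a call that ended without mesenchymal library 1 (-0.98), and Nkx2-1 did not pass (-0.37 ± 0.16, adjusted p = 0.0551).

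All 20 alveolar type 2 genes fell (median -2.94, camera adjusted p = 9.47e-08, or 0.205 with an estimated correlation). They included Hc (-5.27 ± 0.61), Chil1 (-5.11 ± 0.60) and Acoxl (-4.71 ± 0.59). Of 19 alveolar type 1 genes 18 fell and 1 rose (median -3.12, adjusted p = 1.62e-14, or 0.0249 likewise). They included Col4a3 (-3.97 ± 0.34), Rtkn2 (-3.05 ± 0.23) and the vessel growth factor Vegfa (-2.33 ± 0.18, 1135 ± 252.4 to 225 ± 29.4 CPM). Of 36 multiciliated genes 27 fell and 1 rose (adjusted p = 0.000286, or 0.653 likewise). Of 14 club cell genes 12 fell and 1 rose (adjusted p = 0.00212, or 0.305 likewise). All 16 lipofibroblast genes fell (median -1.43, adjusted p = 9.33e-10, or 0.0238 likewise). They included Enpp2 (-2.57 ± 0.20), Npnt (-1.83 ± 0.14) and Tcf21 (-1.57 ± 0.13). Of 16 endothelial genes 15 fell (adjusted p = 9.47e-08, or 0.174 likewise). Pecam1 was at -1.13 ± 0.14. Of 13 pericyte genes 11 fell (adjusted p = 1.31e-05, or 0.0893 likewise). Of 12 mesothelial genes 10 fell (adjusted p = 0.000286, or 0.205 likewise). Msln was at -3.94 ± 0.49. Of 19 leukocyte genes 18 fell (adjusted p = 2.55e-05, or 0.205 likewise). All 9 glucocorticoid-responsive genes fell (median -2.48, adjusted p = 5.29e-06, or 0.158 likewise).

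All 37 mitotic genes rose in mesenchymal lungs (median 1.82, adjusted p = 4.63e-32, or 0.0893 with an estimated correlation). They included Cdc6 (2.76 ± 0.22). Of 40 let-7 targets 27 rose and 6 fell, or 28 and 6 adjusted over the list alone (median 0.92, adjusted p = 1.67e-07, or 0.0249 with an estimated correlation). They included Mycn (2.44 ± 0.21), Igf2bp1 (1.87 ± 0.17) and Ccnd2 (1.55 ± 0.11). Ribosomal protein genes (56 risers of 83), sterol genes (17 and 7 fallers of 27) and imprinted genes (7 and 2 of 11) shifted upward at adjusted p from 1.59e-06 to 0.0369, and from 0.205 to 0.604 with an estimated correlation. The growth factor Igf2 rose by 1.64 ± 0.28 and H19 by 1.73 ± 0.20. Lin28a, Kif12 (6.76 ± 0.34, 0.265 ± 0.172 to 31.6 ± 12.49 CPM), B4galnt4 (4.99 ± 0.32), Crabp2 (4.59 ± 0.39), Kcnk16 (4.56 ± 0.42), Ntm (4.41 ± 0.34), Sept3 (4.38 ± 0.30), Dusp9 (4.28 ± 0.32), the adhesion gene Cntn4 (4.17 ± 0.46) and Epha8 (3.95 ± 0.47) rose most. After Aqp5, Scgb3a1 (-7.53 ± 1.95), Fos (-7.12 ± 1.47, and -2.42 with control replicates 3 to 5), C6 (-6.79 ± 0.74), Scgb1a1 (-6.62 ± 0.79), Lyz1 (-6.54 ± 0.81), Gdpd2 (-6.25 ± 0.83), Pon1 (-6.20 ± 0.65), Wnt3a (-6.11 ± 0.66) and the neuropeptide gene Pnoc, with 3 counts (87.5-fold lower, 95% interval 29.8 to 426), fell most. Without mesenchymal library 1 Wnt3a was at -10.7 and Pnoc at -10.1. Immediate early genes, all 10 lower (median -3.42, adjusted p = 0.0643), gave 5 fallers without controls 1 and 2. In that fit 9 of 10 hepatocyte genes were higher (median 4.42, adjusted p = 0.0448, or 0.627 with an estimated correlation), which followed mesenchymal library 1 (mean log2 CPM 2.11) and not library 2 (-1.31, against -1.92 to -1.59 in controls 3 to 5). In the fit 20 alveolar type 2 genes (median -2.79) and 18 alveolar type 1 genes fell and 37 mitotic genes rose.

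Epithelial and mesenchymal lungs (n = 3 and n = 2) differed in 9771 genes, 4853 higher and 4918 lower in the former. Place, line and Lin28a level (0.98 ± 0.43, not called) were not separated. Aqp5 was 297 ± 132 CPM in epithelial lungs (log2 fold 9.20 ± 0.68, edgeR adjusted p = 2.56e-11). Serpina3n, a protease inhibitor, had 457 counts against 1 (360-fold, 95% interval 64.3 to 14240), Krtap17-1 had no counts in mesenchymal lungs (at least 59.8-fold higher), and Scgb3a1 (7.73 ± 1.99, and 4.73 without epithelial library 3) and Nr4a3 (7.57 ± 0.77) were higher too. Epha8 (-4.46 ± 0.58), Kif12 (-4.42 ± 0.33), Kcnk16 (-4.16 ± 0.47), B3galt5 (-4.002 ± 0.42) and Slitrk6 (-3.98 ± 0.50) were lower. Of 20 alveolar type 2 genes 18 were higher in epithelial lungs (median 2.78, camera adjusted p = 1.83e-05, or 0.44 with an estimated correlation). So were 18 of 19 alveolar type 1 genes (median 2.64, adjusted p = 1.51e-11, or 0.0654 likewise) and all 9 glucocorticoid-responsive genes (median 3.48, adjusted p = 4.39e-10, or 0.0654 likewise). All 37 mitotic genes were lower (median -1.61, adjusted p = 9.95e-22, or 0.299 likewise). Of 9 p53 targets 5 were higher (adjusted p = 0.00111, or 0.0857 likewise).

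Global lungs differed from epithelial lungs in 11568 genes, 5742 higher and 5826 lower. Place, line and Lin28a level (log2 fold -0.84 ± 0.33, edgeR adjusted p = 0.0263) were not separated. Lin28b was higher (3.115 ± 0.60), and Nkx2-1 (-0.65 ± 0.14) and Wt1 (-0.75 ± 0.26) were lower. Kif12 (log2 fold 4.67 ± 0.30), Sall4 (4.64 ± 0.58), Epha8 (4.34 ± 0.53), Kcnk16 (4.25 ± 0.43) and the X-linked gene Xlr3a (5.03 ± 1.21) were higher. Aqp5 (-9.91 ± 0.48, edgeR adjusted p = 8.09e-16), Nr4a3 (-7.55 ± 0.52), Mucl3 (-7.29 ± 0.36), Serpinb9b (-6.98) and C6 (-6.95) were lower in global lungs. All 20 alveolar type 2 genes were lower (median -3.17, camera adjusted p = 1.03e-07, or 0.304 with an estimated correlation), and so were 18 of 19 alveolar type 1 genes (median -3.04, adjusted p = 4.43e-14, or 0.042 likewise) and all 9 glucocorticoid-responsive genes (median -3.41, adjusted p = 3.48e-11, or 0.042 likewise). Mitotic genes were higher, 37 of 37 (median 1.65, adjusted p = 1.79e-18, or 0.304 likewise).

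Log2 folds of the global and mesenchymal comparisons correlated across 18319 genes with Pearson's r of 0.91, genes not being independent replicates. Shared controls alone gave a mean r of 0.376 in simulations of this pair. The covariance was 1.29 against 0.056 in the simulations, and 4768 genes were higher and 4674 lower in both, where 1609 and 1616 would be shared by independent calls, with 4 opposite. For global and epithelial lungs r was 0.268, below the simulated mean of 0.432, and the covariance 0.252 against 0.056 simulated, with 1446 genes higher and 1240 lower in both, 1056 and 912 for independent calls, and 1521 opposite. For epithelial and mesenchymal lungs r was 0.275, below the simulated mean of 0.326, and the covariance 0.254 against 0.058, with 1298 and 1069 shared and 1261 opposite. Each comparison was also given its own controls (1 and 2 for one, 3 to 5 for the other). Then r was 0.772 and 0.726 for global and mesenchymal lungs (covariance 1.24 and 1.21). It was 0.015 and 0.235 for global and epithelial lungs (0.017 and 0.26), and 0.264 and 0.002 for epithelial and mesenchymal lungs (0.284 and 0.003). So the covariance of pairs with epithelial lungs depended on the controls used. Independent calls leave out shared controls.

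Steps between control stages were tested too. The gene model Gm1821, chosen after its values were seen, was at 18.9 to 27.0 CPM in all E12.5 and E16.5 libraries, E14.5 global 4, E18.5 controls 1 and 2 and E18.5 global 1, 2, 4 and 5, and at 0.0795 to 0.735 in all others. The sets coincide with the first and second steps and partly with comparisons of E14.5 global or E18.5 control or global lungs. These folds also compare the sets, and the cause was not tested. From E12.5 to E14.5 (3060 genes, 2062 higher and 998 lower), Cyp2f2 went from 0.161 to 28.6 CPM (log2 fold 7.40 ± 0.96, edgeR adjusted p = 2.49e-06), the airway lipid-binding gene Sec14l3 was at least 107-fold higher, and the leukocyte genes Gzma, H2-Aa and Cd3g appeared. Thymus-carrying control 3 held 98.4%, 92.9% and 99.5% of their CPM, and without the doubted libraries only H2-Aa was called of them (5.89 ± 1.29). Stra6 (-3.27 ± 0.38), Igfbpl1 (-3.67 ± 0.57), Hsd3b6 (-3.43 ± 0.52), Rims2 (-3.32 ± 0.91) and Alpk2 (-3.74 ± 1.13) fell. Alpk2, in E12.5 controls in the order of the cardiac Myh6, lost its call without E12.5 control 2 (-2.75), E14.5 control 1 (-3.80) or E14.5 control 2 (-3.18), and Rims2 without E14.5 control 2 (-3.00). From E14.5 to E16.5 (6579 genes, 3321 higher and 3258 lower), Slc34a2 went from 4.70 to 639 CPM (7.08 ± 0.91), Scgb1a1 rose by 7.16 ± 0.98, Sftpd by 7.02 ± 1.03, Mlc1 562-fold (95% interval 100.3 to 22220) and Retnla 219-fold (95% interval 74.5 to 1065). The neuronal tubulin Tubb3 (-5.02 ± 0.63), Bcat1 (-3.75 ± 0.55) and Zfp990 (124-fold, 95% interval 33.99 to 1027) fell. Zfp990 was also split within E18.5 controls (0 to 0.161 CPM in 1 to 3, 5.38 and 4.09 in 4 and 5). Arpp21 and the keratin Krt17 fell as well (-4.26 ± 1.03 and 165-fold, 95% interval 45.3 to 1364), but E14.5 control 3 held 93.1% and 91.6% of their CPM, and without the doubted libraries Arpp21 was not called (-1.02) and Krt17 was at -4.16. From E16.5 to E18.5 (6645 genes, 3137 higher and 3508 lower), Scgb3a1 (8.17 ± 1.75), the antimicrobial lectin Reg3g (7.19 ± 1.76), Fos (6.72 ± 1.19), Pon1 (6.32 ± 0.56) and Lyz1 (5.89 ± 0.64) rose. Without the doubted libraries Fos was at 2.02, Scgb3a1 at 6.89 and Reg3g at 5.62, all called, and without E16.5 control 3 Reg3g was at 10.83. The bone matrix gene Ibsp (-3.50 ± 0.37), Nxpe4 (-3.28 ± 0.36), Crh (-3.10 ± 0.52), the chemokine Ccl11 (-3.01 ± 0.30) and the complement factor Cfi (-2.55 ± 0.30) fell. Alveolar type 2 genes rose in 12, 19 and 13 of 20 cases over the 3 steps (camera adjusted p = 1.44e-12, 1.06e-15 and 2.62e-05, adjusted p = 0.108, 0.132 and 0.396 with an estimated correlation). Mitotic genes fell in 30 and then all 37 of 37 cases over the last 2 steps (adjusted p = 7.49e-10 and 1.27e-48, adjusted p = 0.432 and 0.0611 likewise). Let-7 targets fell in 10 and rose in 1 of 40 cases in the first step (adjusted p = 1.16e-07, or 0.0285 likewise) and fell in 17 and rose in 7 in the last (adjusted p = 0.0408, or 0.397 likewise).

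Whether the global effect itself differed between stages was tested as an interaction. Without 1 library the 3 tests gave 1 to 156, 745 to 1473 and 1003 to 2619 called genes. From E12.5 to E14.5, 8 genes were called: Hmga2 (1.37 ± 0.24, edgeR adjusted p = 0.0132), Shisa3 (3.21 ± 0.48), Epha8 (2.86 ± 0.55), Stra6 (2.48 ± 0.49) and Cnr1 (2.43 ± 0.41) towards higher, the receptor kinase Kit (-1.13 ± 0.20) towards lower. Shisa3 went from -1.08 to 2.13 and Kit from 0.19 to -0.94. Shisa3 stayed called without any 1 library. Calls ended without E12.5 global 3 or E14.5 control 3 for Hmga2 (1.41, 1.27), Epha8 (2.74, 2.84), Stra6 (2.42, 2.43), Cnr1 (2.36, 2.21) and Kit (-1.10, -1.15), and without E14.5 control 2 for all of these but Cnr1 (1.34, 2.62, 2.32, -1.12). Kit also lost its call without E12.5 control 3 (-0.98), Epha8 without E12.5 control 1, control 2 or global 2 or E14.5 global 1 (2.34 to 2.92), and Stra6 without E12.5 controls 1 to 3, E12.5 global 2 or E14.5 global 1, 3 or 4 (2.28 to 2.54). From E14.5 to E16.5, 1443 genes were called, 734 towards higher and 709 towards lower: Kif12 (2.99 ± 0.36, adjusted p = 4.59e-05), Bcat1 (3.15 ± 0.68) and Crabp2 (2.98 ± 0.50) towards higher, the surfactant protease Napsa (-6.26 ± 1.29), Aqp5 (-5.13 ± 1.16), Dlk2 (-4.57 ± 0.74) and Gipr (-4.42 ± 0.91) towards lower. The thymus gene Prss16 (6.27 ± 1.38) and the kidney-type gene Fxyd2 (-4.98 ± 1.58) were among them. Without E14.5 control 3 Prss16 was at 1.80, and without E14.5 global 4, where Napsa was at 98.5 CPM against 2.22 to 2.79 in the other 3, Napsa was at -2.83 and Fxyd2 at -2.46, none called. Fxyd2 also lost its call without any E14.5 control or E16.5 library (-4.29 to -5.27). Cntn2 was called too, with no counts in E16.5 controls. Alveolar type 2 genes gave 9 members shifted towards lower, or 14 adjusted over the list alone (median -2.23, camera adjusted p = 1.64e-13, or 0.196 with an estimated correlation). From E16.5 to E18.5, 1957 genes differed, 1290 towards higher and 667 towards lower: Ibsp (4.22 ± 0.53, adjusted p = 2.56e-05), Crh (3.65 ± 0.74), Kif12 (3.48 ± 0.48), Ccl11 (2.997 ± 0.43) and Nxpe4 (2.96 ± 0.49) towards higher. Fos (-6.29 ± 1.70), Atf3 (-6.22 ± 1.62), Pon1 (-6.03 ± 1.85), the macrophage receptor Marco (-4.64 ± 1.25) and Rasgrf2 (-4.53 ± 0.98) shifted towards lower. Without the doubted libraries 880 were called, and Fos (-1.57), Atf3 (-1.54) and Marco (-3.92) were not called. Fos lost its call without E16.5 global 2, Marco without global 3 and Pon1 without control 3, global 1 or global 2, their folds then being -6.18, -4.44 and -5.20 to -6.02. All 37 mitotic genes shifted upward (median 1.21, adjusted p = 1.55e-42, or 0.193 with an estimated correlation).

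The maturation score, taken from genes that change between control stages, placed global lungs below their controls from E14.5 on. The difference from controls was -0.16 at E12.5 (-3.79 ± 0.217 against -3.63 ± 0.078, n = 3 and n = 3; exact permutation p = 0.3). It was -1.004 at E14.5 (-2.62 ± 0.194 against -1.62 ± 0.025, n = 4 and n = 3; exact permutation p = 0.0571, the smallest this design allows) and -2.44 at E16.5 (-2.61 ± 0.17 against -0.17 ± 0.37, n = 3 and n = 3; exact permutation p = 0.1, also the smallest possible). At E18.5 it was -3.09 in global lungs (0.94 ± 0.332 against 4.03 ± 0.191, n = 5 and n = 5; exact permutation p = 0.00794, the smallest possible). It was -0.10 in epithelial lungs (3.93 ± 0.068, n = 3; exact permutation p = 0.5) and -2.90 in mesenchymal lungs (1.136 ± 0.666, n = 2; exact permutation p = 0.0952, the smallest possible). After Benjamini-Hochberg adjustment over the 6 exact permutation tests the values were 0.36, 0.15, 0.15, 0.0476, 0.5 and 0.15. Of the 200 genes that rise between control stages, 131 fell at E14.5, 190 at E16.5 and 191 at E18.5 in global lungs (camera p = 7.95e-55, 3.59e-87 and 1.62e-53, and p = 0.0037, 0.000462 and 0.00289 with an estimated correlation). Of the 200 that fall, 53, 193 and 178 rose (camera p = 6.88e-23, 1.76e-63 and 9.44e-46, and p = 0.0679, 0.00558 and 0.000643 with an estimated correlation), so at E14.5 only the first set passed with it. In epithelial lungs 40 of the first were lower and 43 higher, and 26 and 49 of the second (camera p = 0.945 and 0.162, and p = 0.989 and 0.706 with an estimated correlation). In mesenchymal lungs 185 of the first were lower and 173 of the second higher (camera p = 7.69e-45 and 3.27e-47, and p = 0.00512 and 0.000693 with an estimated correlation).

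**Figure D4:**
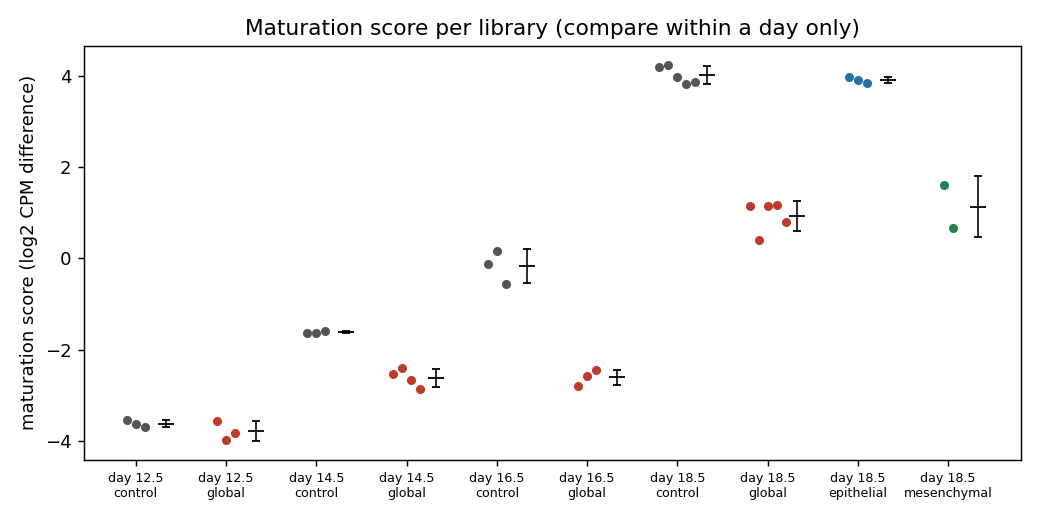
Maturation score of each library (points, mean log2 CPM of stage risers less that of stage fallers) with group mean and SD (bars) beside them, scores being comparable within a day only. E18.5 means are 4.03 in controls, 0.94 in global, 3.93 in epithelial and 1.136 in mesenchymal lungs.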

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

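The tests of depth, of epithelial share, of heart tissue and of the immediate early state were chosen after the results were seen, while the stage test of alveolar type 2 genes was planned. In groups of 4 or 5 libraries, a library lay far from its group in 12 of 95 values for E14.5 global lungs, 7 of 147 for E18.5 controls and 12 of 95 for E18.5 global lungs, where chance gives about 5%. Each gap is given below as its share of the group's range.

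In E14.5 global lungs, library 4 was far above the others for the kidney-type genes Kap (0.986), Fxyd2 (0.953) and Miox (0.911), for Hmga2 (0.947, 529 CPM against 353 to 363) and for the red cell genes Slc4a1 (0.941), Hbb-bh1 (0.841) and Hbb-y (0.832, 1295 CPM against 81.3 to 285). Library 1 was far above for Rps3a3 (0.886) and Epha8 (0.867), and library 2 for Sec14l3 (0.911), Bmp4 (0.834) and Gabrp (1, the lone count). In E18.5 controls, library 4 stood above for Dusp9 (0.86), Nkx2-1 (0.848, 898 CPM against 626 to 667) and Igf2 (0.734), library 2 above for Cyp2e1 (0.85) and below for Cntn4 (0.815), and library 3 below for Gyg (0.782) and alone in having Sall4 counts (1). In E18.5 global lungs, library 2 stood below for Npnt (0.874) and Abca3 (0.81, 52.8 CPM against 122 to 138) and above for Grb10 (0.732), and library 5 below for Dusp9 (0.831), Ccnd2 (0.821) and Cdkn1c (0.71) and above for Cdc6 (0.821), Enpp2 (0.74) and Gucy1a1 (0.729). Library 1 stood above for Higd1b (0.736) and Rtkn2 (0.731) and library 4 above for Lin28a (0.719, 744 CPM against 448 to 531).

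Global effects differed between successive stages in 8, 1443 and 1957 genes. Epithelial lungs differed from mesenchymal lungs in 9771 and from global lungs in 11568.

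Alveolar type 2 genes were lower in E18.5 global and mesenchymal lungs. A smaller epithelial share would lower general epithelial genes as well, but 30 of these had medians of -0.231 (quartiles -0.587 and 0.584) in global and -0.285 (-0.655 and 0.477) in mesenchymal lungs. The shallow libraries, replicates 1 and 2, do not carry the fall of the list, since the list medians were -3.049 and -2.788 without them. Nor did the lungs stand at the stage of E16.5 controls, against which the medians were -2.017 and -1.525. A changed epithelial share, a stage before that of E16.5 controls and a lower expression of these genes within the epithelium may remain as hypotheses. None was tested in separated cells.

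Cardiomyocyte genes were lower in E12.5 global lungs. The global libraries differed by 4.45 in mean log2 CPM, as heart tissue carried along with some lungs could give, and only 2 of the 3 lay below the lowest control, which argues against a fall in all global lungs. Immediate early genes were lower in E18.5 global lungs, but the median was -0.61 with replicates 3 to 5, so the state of control replicates 1 and 2, such as handling before freezing, may account for most of it. No biological explanation was tested for either.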

How the results depend on the processing

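Embryo sex as a term, E18.5 replicates 3 to 5 only and the fits without doubted libraries were chosen after the data were seen. Of 6923 values of named genes under the alternatives, 6708 kept direction and side of the threshold, 204 lost and 8 gained their call and 3 reversed. Of 560 list results, 430 held, 103 lost and 27 gained their call and 0 reversed. For 9 named values DESeq2 gave no adjusted p. The 3 reversals came without E14.5 control 3, the library with thymus transcripts: Rag1 turned to 0.242, Themis to 0.549 and Lck to 0.433, none called. Without another library the lowest log2 folds were -8.694, -5.787 and -2.145.

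At E12.5 the 41 called genes became 26 without the filter on low counts, 141 with DESeq2, 13 with only the compared groups in the fit, 25 with 1 surrogate variable, 25 with a replicate block and 27 with embryo sex as a term. At E14.5 the replicate block gave 1319, although same-numbered libraries were not correlated (-0.106 to -0.007), so the numbers do not pair samples. Only the compared groups gave 3336 in epithelial lungs and 3017 for the E16.5 against E14.5 interaction. The E14.5 against E12.5 interaction gave 49 genes with DESeq2, 22 with only the compared groups and 4 with the replicate block, and that of E18.5 against E16.5 gave 912 with replicates 3 to 5. The cause of these changes was not tested.

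Leaving out 1 library in turn gave 8 (without control 3) to 361 (without global 1) genes at E12.5, 1263 (without control 3) to 2282 at E14.5, 6588 to 10085 in mesenchymal lungs, and for the interactions 1 to 156 (without E12.5 global 1), 745 to 1473 and 1003 to 2619. At E16.5 the range was 5314 to 6241, in E18.5 global lungs 11299 to 11832 and in epithelial lungs 4353 to 6693. Where 1 mesenchymal library was left, it was assumed to vary like the other groups. The correlations ran from 0.224 to 0.327 for global and epithelial, 0.831 to 0.917 for global and mesenchymal and 0.233 to 0.34 for epithelial and mesenchymal lungs. Without the filter the global and mesenchymal one was 0.862, and with replicates 3 to 5 the ones with epithelial lungs were 0.219 (global) and 0.222 (mesenchymal), the cause not being tested.

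The epithelial maturation difference turned to 0.458 (exact permutation p = 0.3) on the axis from E18.5 control replicates 1 and 2, while both values lay inside what relabelling gives. With the correlation estimated per list, 1 of 35 lists passed at E12.5, 2 at E14.5, 4 at E16.5, and 3, 2 and 3 in E18.5 global, epithelial and mesenchymal lungs, and fry passed 3 at E12.5. In simulated data of the same depth and group sizes, 57% to 73% of 2-fold and 77% to 90% of 4-fold changes were recovered, with 4 to 10 false calls, so part of the changes of these sizes was missed.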

Other observations

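The test of let-7 seed matches was planned with its prediction, and the count at E12.5 was chosen after the genes were seen. If Lin28A acts through let-7, genes with the 8-base seed match in the 3' UTR should rise. The 549 genes with it, of 15203, exceeded the others in median log2 fold by 0.074 at E12.5 and 0.126 at E14.5 (rank 1 among 105 words of the same base composition in each), by 0.095 at E16.5 (rank 2) and at E18.5 by 0.071 in global (rank 2), 0.083 in epithelial (rank 4) and 0.065 in mesenchymal lungs (rank 2), all inside the predicted ranks 1 to 5. Without the members of the let-7 list the ranks were 1, 1, 3, 2, 4 and 6, the last outside. At E12.5, 12 of 22 risers and 1 of 19 fallers carried the match (Fisher exact p = 0.00079), Lin28a and let-7 list genes included. Lower let-7 activity could give this, but matched 3' UTRs were longer (median 2442 against 1103 bases).

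Other splits of the same libraries tested for chance. No other split tried was as large for E14.5 (2361 genes, highest other 1206), E18.5 global (11872 and 7944) and epithelial lungs (6077 and 2789). The 2789 had controls 1 to 3 against the rest. Nor was any for controls of E18.5 against E16.5 (6645 and 5474) and global against epithelial lungs (11568 and 6563). Small unadjusted shares do not exclude chance. For the interactions the splits are no test, since those that keep or exchange all labels of a day carry that day's effect. In stage order they gave at most 1609, 4701 and 3655 genes against 8, 1443 and 1957, with 10, 11 and 2 of 100 splits as large. The 10 splits of 3 against 3 libraries are too few for a share under 0.05: E12.5 gave 41 genes and 191 in the highest other split, which points to a structure of these samples, E16.5 gave 6785 and 0, and the first control steps gave 3060 and 0, and 6579 and 0.

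By sex-linked genes, 3 of 3 control and 1 of 3 global embryos were male at E12.5, 2 of 3 and 1 of 4 at E14.5, 1 of 3 and 2 of 3 at E16.5, and at E18.5 1 of 5 controls, 3 of 5 global, 1 of 3 epithelial and 1 of 2 mesenchymal. E14.5 global 2, counted as female, also had the Y-linked Ddx3y at 7.02 CPM, where the other females had 0 to 0.298 and males 43.4 to 99.9. Mixed material is possible there and was not tested.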
